A study of Mus musculus with 6 samples.

How the data were processed

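The scanner files hold fluorescence intensities of 6 one-colour (Cy3) Agilent mouse arrays of one design, all on 1 slide and from 1 scan. Per the file headers, Feature Extraction 10.7.3.1 subtracted the background of each spot intensity and removed a spatial trend, with no normalization between arrays. The series table deposited with them holds linear intensities with the same quantiles in every array (median 20.9), and per the values its ranks correlated with those of the scanner files at 0.99995 or more. The method behind that table is not stated in the deposited records. The labels name RNAiso Plus and the RNeasy Mini kit for RNA extraction and the Low Input Quick Amp kit for labelling. They also name a preculture of 24 hours with SCF at 100 ng/ml, IL-6 at 10 ng/ml and IL-3 at 10 ng/ml before the cells were infected. The BCR-ABL vector carried GFP and the Irf8 vector a truncated human CD8, and the cells were sorted by flow cytometry. Human BCR-ABL cDNA and mouse Irf8 cDNA were used, and the Flt3L was human.

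Each array had 62976 spots, of which 3671 were controls, and 55681 distinct probes. Of the probes 26762 were given a gene symbol through their accession in a RefSeq table of assembly GRCm38.p6, used for names alone (20284 symbols), and 28919 kept another name. Control spots and spots marked as population or non-uniformity outliers were left out, which removed 47 probes. The array's 75th percentile of signal was 258 to 347, and the logged signals of the spike-in controls followed their known amounts with an r2 of 0.991 to 0.994. Arrays give no counts, so their number and the signal over background limit the precision. Cells with IRF8 alone, the protein level of either transgene and the genome are not analysed here.

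Log2 of the processed signal had the log2 of its array's 75th percentile over all non-control probes subtracted. Spots of a probe were averaged, and a gene was read from its brightest probe over the 6 arrays. Genes were kept when that probe was well above background on both arrays of at least 1 group, which left 22762, of which 13985 had a symbol. All 6 samples entered 1 linear model in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with a mean per group, moderated variances and 5.28 degrees of freedom. P values were adjusted by Benjamini-Hochberg over the genes of a comparison, two-sided, at a threshold of 0.05, and a call means a gene or list past it. A gene dim in a group, not well above background on either of its arrays, has a fold computed against the background level, as a bound. Where its probes differed by more than a log2 of 2 in the change, the other probe's value is given.

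For gene sets, 25 lists of 5 or more tested genes were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison. They cover plasmacytoid DCs, conventional DC type 1, general and type 2 conventional DCs, MHC class II presentation, monocytes and macrophages, neutrophils, basophils and mast cells, eosinophils, erythroid cells, megakaryocytes, B cells, T and NK cells, and stem and progenitor cells. The others are STAT5 targets, ERK targets, cell cycle, interferon response, genes that IRF8 activates, cytokines and chemokines, myeloid transcription factors, glycolysis, cholesterol synthesis, ribosome biogenesis, pro-apoptotic genes and the ATF4 response. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without regard to other genes, were run beside it.

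The samples, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Irf8, Abl1 and Bcr, and in each comparison the 8 largest rises and 8 largest falls among called genes. These needed the same sign in both experiments, a symbol other than a clone or predicted name, and a probe well above background on all arrays compared. The rule adds the 3 largest rises and 3 largest falls by bound, up to 4 members of each list with the smallest p, and the 6 genes with the largest summed change in each direction among those called in opposite directions. Alternatives were other scalings, the series table, normexp background correction with an offset of 50, other filters and probe summaries, another variance model, a larger change as threshold, the experiment as a block, only the groups compared, and each sample left out in turn. Normexp used the median spot signal because the files hold no mean signal.

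The labels give each group a sample of experiment 1 and of experiment 2, and the series record speaks of independent experiments, so equal numbers were taken to pair samples. Deviations from the group means within experiments correlated across genes at 0.04 between empty vectors and BCR-ABL, -0.11 between empty vectors and BCR-ABL+IRF8, and 0.01 between BCR-ABL and BCR-ABL+IRF8. The block left 4.34 degrees of freedom.

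The fit was tested on simulated data of this layout, with 100 genes raised or lowered by a log2 of 1 and 100 by 2. It recovered 5% of the smaller changes in all 3 comparisons and 77%, 75% and 75% of the larger. False calls were 3, 7 and 3 of 22762 genes. A raised cell cycle list was called each time, with 0, 1 and 0 of 24 others. Far more genes were called in the data, where recovery was not measured.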

Results

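RNA of cultured mouse bone marrow cells was profiled on 6 single-colour Agilent expression arrays. The starting cells were lineage-negative (Lin-) cells, the immature fraction of marrow that lacks surface markers of mature blood cells. They received 2 retroviral vectors, were sorted, and were then kept for 5 days in 100 ng/ml Flt3L, the cytokine that drives dendritic cell (DC) development from such precursors. The 3 groups of 2 samples carried both empty vectors, human BCR-ABL with the other vector empty, or BCR-ABL with mouse Irf8. BCR-ABL is the fusion tyrosine kinase of chronic myeloid leukaemia, and IRF8 is a transcription factor needed for DC and monocyte development. Each group had 1 sample from each of 2 independent experiments. Between 28644 and 30207 of 55681 probes per array were well above background, 51.4% to 54.3%, and no spot was saturated. Replicate arrays correlated across the 22762 genes tested with r of 0.989 for empty vectors, 0.993 for BCR-ABL and 0.977 for BCR-ABL with IRF8 (genes are not independent replicates). More than 2-fold apart between replicates were 1028, 425 and 2587 genes in the same order.

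Values in parentheses after a gene are log2 differences ± SE from the limma fit, with n = 2 samples per group. A gene well above background on neither array of one group and on both of the other is given as "at least N-fold", a lower bound. Arrays on which a gene was "seen" had it well above background, and counts of members are of those tested. Counts "over the list alone" use p adjusted within the list. A dagger marks a gene named after its values were known, outside the rule for named genes. The block is the experiment number added to the fit, and its value stands beside a result where it ended a call or moved a count by more than 1.5 times. Members of families with near-identical copies are uncertain, because a probe can report a paralog. They include the Ear, Rnase2, Chil, Klk1, Gzm, Hba, Hbb, Crisp, Lyz and Tpsb genes.

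The overexpressed gene was read first. Irf8 had log2 signals of 7.81 and 8.0 above the array's 75th percentile in the empty-vector samples and 3.81 and 3.98 in the BCR-ABL samples. In the BCR-ABL+IRF8 samples they were 6.82 and 5.98. The signal fell 16.1-fold with BCR-ABL (-4.01 ± 0.30, adjusted p = 0.00123) and was 5.67-fold higher again with the Irf8 vector (2.50 ± 0.30, adjusted p = 0.0118). It stayed 2.84-fold below the empty-vector level (-1.51 ± 0.30, adjusted p = 0.0361, blocked adjusted p = 0.0693). That last call was also lost without the filter on dim probes (adjusted p = 0.0767), with only the 2 groups compared (0.0900), and without either empty-vector sample (0.140 and 0.156) or either BCR-ABL sample (0.0900 each). The rise with the Irf8 vector missed the threshold without BCR-ABL replicate 1 (0.0868) or replicate 2 (0.0837). Whether the Irf8 probe lies within the transduced cDNA is not known here, so the signal may hold the endogenous transcript, the vector's, or both. Whether the mouse probes for Abl1, the tyrosine kinase gene, and Bcr, its partner in the fusion, report the human cDNA was not tested. Abl1 fell with BCR-ABL (-0.62 ± 0.14, blocked adjusted p = 0.0540) and was lower than with empty vectors in BCR-ABL+IRF8 cells (-0.72 ± 0.14, blocked adjusted p = 0.0728). Bcr fell with BCR-ABL (-1.23 ± 0.22) and did not pass the test in the other comparisons (0.60 ± 0.22 against BCR-ABL and -0.63 ± 0.22 against empty vectors), nor did Abl1 between BCR-ABL+IRF8 and BCR-ABL (-0.10 ± 0.14).

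**Figure D1:**
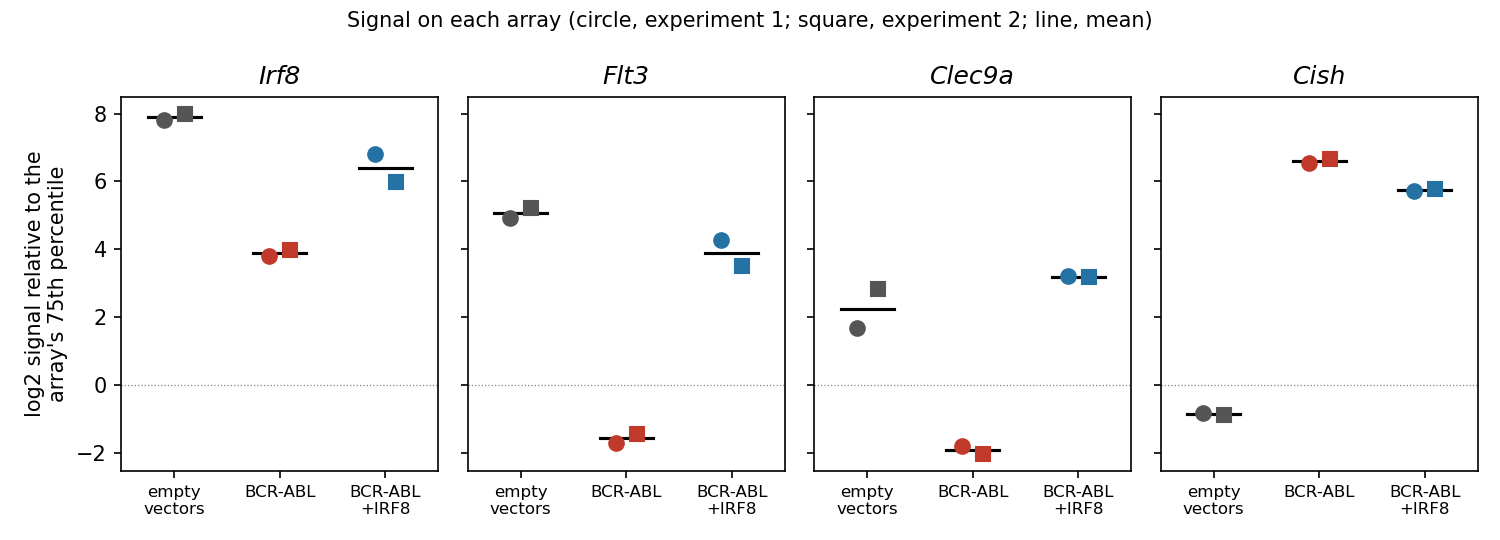
Log2 signal relative to the array's 75th percentile for Irf8, Flt3, Clec9a and Cish in each of the 6 arrays, by group; circles are experiment 1, squares experiment 2 and lines group means. Irf8 sits at 7.81 and 8.0, 3.81 and 3.98, and 6.82 and 5.98 in the 3 groups.

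The first comparison asked what BCR-ABL does to cells placed under conditions for DC development. Flt3, the receptor for the culture's cytokine, fell 100.1-fold (-6.65 ± 0.29, n = 2 per group), and of the genes of conventional type 1 DCs and plasmacytoid DCs 9 of 12 and 7 of 15 fell with it, while 1 in each list rose. Those 2 lists and cell cycle genes (median log2 difference -2.61) passed the test downward, and genes of mast cells, red cell precursors and megakaryocytes upward (medians 3.79, 3.76 and 3.11; erythroid 1.33 with normexp correction). None of these 6 lists passed with an estimated correlation (adjusted p = 0.625 each). Cytokine and chemokine genes and targets of STAT5, a transcription factor that BCR-ABL activates, passed upward as well (adjusted p = 0.371 each with an estimated correlation), and Cish, a STAT5 target, rose 176-fold (7.46 ± 0.14).

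Among single genes well above background in both groups, the largest rises were Fbp1 (11.85 ± 1.01), a gluconeogenic phosphatase, Ccl24 (11.14 ± 0.57), an eosinophil chemokine, Rbp4 (10.77 ± 0.89), the retinol carrier, and Arg1 (9.27 ± 1.34), arginase. They were followed by Chil4 (9.19 ± 0.52), a chitinase-like protein, Gstt1 (8.70 ± 0.31), a glutathione transferase, Ccl17 (8.58 ± 0.40), a chemokine for T cells, and Rnase2a (8.38 ± 0.45), an eosinophil ribonuclease. The largest falls were Klrd1 (-8.46 ± 0.22), the CD94 chain of natural killer receptors, Adgrg5 (-6.98 ± 0.27), an adhesion receptor, Upb1 (-6.82 ± 0.54), an enzyme of pyrimidine breakdown, and Dpp4 (-6.70 ± 0.27), a surface peptidase. Flt3 (-6.65 ± 0.29), Tlr12 (-6.59 ± 0.22), a Toll-like receptor, Klrb1f (-6.50 ± 0.27), a lectin-like receptor, and Kif5a (-6.27 ± 0.18), a kinesin, completed them. A second Kif5a probe gave -2.07. Of genes dim in one group, Crisp3 (at least 610.4-fold higher), Tph1 (at least 357-fold higher), an enzyme of serotonin synthesis, and Slc7a2 (at least 246-fold higher), a transporter of cationic amino acids, rose most. Ctnnd2 (at least 599.6-fold lower), a catenin, Cx3cr1 (at least 482-fold lower), the fractalkine receptor, and Btla (at least 446-fold lower), an inhibitory receptor, fell most.

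In the list for conventional DC type 1, the subset that cross-presents antigen, 9 of 12 members fell and 1 (0 with the block) rose, with 2 up and 9 down over the list alone. Type 1 DC genes had a median of -3.51, or -3.02 with dim members at bounds, with camera adjusted p = 0.00122, and adjusted p = 0.625 with an estimated correlation. Their median was -1.69 with normexp correction. Clec9a (-4.16 ± 0.38), Tlr3 (at least 18.6-fold lower), Wdfy4 (-2.70 ± 0.30) and Cadm1 (at least 9-fold lower) were among those that fell; Clec9a is a receptor for dead cells and Tlr3 a receptor for double-stranded RNA. Batf3† (1.46 ± 0.40, blocked adjusted p = 0.0747), a transcription factor of that subset, rose. The list's call was lost when only probes seen on all 6 arrays were kept (0.108). For plasmacytoid DCs, the producers of type I interferon, 7 of 15 members fell and 1 rose, as many over the list alone. Plasmacytoid DC genes had a median of -1.49, with camera adjusted p = 0.00166, and adjusted p = 0.625 with an estimated correlation. Their median was -0.88 over probes seen on all arrays and -3.46 with the mean of a gene's probes. Spib (-6.20 ± 0.24), Ly6d (-8.33 ± 0.51, seen on 1 of 2 BCR-ABL arrays), Tcf4 (-3.05 ± 0.23) and Upb1 (-6.82 ± 0.54) fell, of which Spib and Tcf4 are transcription factors of the lineage, and Klk1† (4.82 ± 1.14) rose. Across general and type 2 conventional DC genes 8 of 16 members fell and 5 rose, with 6 up and 9 down over the list alone. General and type 2 DC genes had a median of -1.01, with camera adjusted p = 0.174. Btla (at least 446-fold lower), Kmo (-5.45 ± 0.17) and Flt3 (-6.65 ± 0.29) were among the members that fell, while Ccl17 (8.58 ± 0.40), Irf4 (2.11 ± 0.25), Itgax† (2.37 ± 0.38), Mgl2† (2.31 ± 0.41) and Ccl22† (1.65 ± 0.41) rose. Of the genes for MHC class II presentation 6 (3 with the block) of 15 members fell and 1 rose, with 2 up and 9 down over the list alone. MHC class II genes had a median of -1.13, with camera adjusted p = 0.00572, and adjusted p = 0.638 with an estimated correlation. Ciita (-3.11 ± 0.33), H2-Ob (-3.56 ± 0.53) and H2-Oa (-3.16 ± 0.57) were the falls named by the rule, Ciita being the master regulator of the class, and Lgmn (1.94 ± 0.41) rose.

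Lists of other blood lineages moved apart. 11 of 15 members rose in the basophil and mast cell list, as many over the list alone, including Il13 (at least 84.5-fold higher), Mitf (3.15 ± 0.24), Mcpt4 (at least 14.9-fold higher) and Tpsb2 (4.02 ± 0.41). Basophil and mast cell genes had a median of 3.79, with camera adjusted p = 7.55e-05, and adjusted p = 0.625 with an estimated correlation. Empty-vector list medians were -1.94 and 0.76. Of erythroid genes 13 of 19 members rose, as many over the list alone; Hbb-bt (7.04 ± 0.51), Cited4 (4.39 ± 0.35), Gata1 (3.93 ± 0.42) and Add2 (at least 6-fold higher) had the smallest p, and Gata1 is the lineage's transcription factor. Erythroid genes had a median of 3.76, or 2.88 with dim members at bounds, with camera adjusted p = 9.12e-05, and adjusted p = 0.625 with an estimated correlation. Their median was 1.33 with normexp correction. Of megakaryocyte genes 12 of 13 members rose, with 13 up over the list alone, such as Vwf (3.92 ± 0.23), Selp (2.36 ± 0.17) and Pf4 (4.29 ± 0.32). Megakaryocyte genes had a median of 3.11, with camera adjusted p = 2.68e-07, and adjusted p = 0.625 with an estimated correlation. The eosinophil list did not pass, although 3 of 9 members rose, as many over the list alone: Ear2 (6.28 ± 0.40), Ear1 (6.03 ± 0.43) and Ear6 (4.30 ± 0.35), all secreted ribonucleases. Eosinophil genes had a median of 0.65, with camera adjusted p = 0.220, and passed upward over probes seen on all arrays (0.0119, median 4.30 of 5 genes). Neither did monocyte and macrophage genes, of which 4 of 18 members rose and 4 fell, with 5 up and 4 down over the list alone. Monocyte and macrophage genes had a median of 0.25, with camera adjusted p = 0.722. Mrc1 (5.22 ± 0.43), Msr1† (3.96 ± 0.62) and Lyz2† (1.78 ± 0.44) were among those that rose, and Cx3cr1 (at least 482-fold lower), Ms4a6c (-2.19 ± 0.28), Mpeg1 (-1.57 ± 0.20) and Ccr2† (-0.89 ± 0.21, blocked adjusted p = 0.0574) fell. Neutrophil genes split too, as 4 of 21 members rose and 2 fell, as many over the list alone: Chil3 (5.20 ± 0.58), Gfi1 (3.71 ± 0.67), Cd177† (2.43 ± 0.54) and Lcn2† (2.42 ± 0.63, blocked adjusted p = 0.0683) were higher, and Prtn3 (-3.64 ± 0.48) and Mpo (-2.91 ± 0.51), granule enzymes of promyelocytes, were lower. Neutrophil genes had a median of 0.91, with camera adjusted p = 0.154, and passed upward without empty-vector replicate 2 (0.00473, median 1.40).

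B cell genes had a median of 0.19, a mean of -0.69 and a test pointing down (camera adjusted p = 0.220). Of them 5 of 11 members fell and 1 (2 with the block) rose, as many over the list alone; Cd79b (-4.41 ± 0.29), Ms4a1 (at least 4.70-fold lower), Blk (at least 3.20-fold lower), Cd22 (-1.76 ± 0.28) and Bank1† (-1.07 ± 0.22) fell, and Il7r† (2.86 ± 0.70), the interleukin 7 receptor, rose. Of T and NK cell genes 5 of 14 members rose and 4 fell, as many over the list alone, with Eomes (at least 4.74-fold higher), Gata3 (at least 6.44-fold higher), Gzma† (5.91 ± 1.02), Thy1† (3.12 ± 0.75) and Il2rb† (2.12 ± 0.53, seen on 1 of 2 empty-vector arrays, blocked adjusted p = 0.0637) higher and Cd5 (-5.26 ± 0.50), Cd2 (-2.67 ± 0.27), Zap70† (-2.55 ± 0.50, seen on 1 of 2 BCR-ABL arrays) and Tcf7† (-1.19 ± 0.33) lower. T and NK cell genes had a median of 0.24, with camera adjusted p = 0.573. Stem and progenitor genes did not pass as a list, while 6 of 17 members fell and 5 rose, as many over the list alone. Stem and progenitor genes had a median of -0.82, with camera adjusted p = 0.330. Myb (-3.53 ± 0.22) and Kit (-3.34 ± 0.29) fell, Kit being the stem cell factor receptor, and Prom1 (3.35 ± 0.24), Mycn (5.28 ± 0.55, seen on 1 of 2 empty-vector arrays), Procr† (2.91 ± 0.33), Meis1† (1.81 ± 0.41) and Gata2† (3.79 ± 0.92) rose. Myeloid transcription factors went both ways: 7 of 16 members rose and 4 fell, as many over the list alone. Myeloid transcription factors had a median of 0.72, with camera adjusted p = 0.508. Cebpb (3.74 ± 0.25) and Irf4 (2.11 ± 0.25) led the rises, and Tcf4 (-3.05 ± 0.23), Ikzf1 (-1.79 ± 0.17), Zbtb46† (-1.51 ± 0.19) and Bcl6† (-2.12 ± 0.27) fell.

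Of 15 STAT5 targets 9 rose and 1 fell, as many over the list alone. STAT5 targets had a median of 2.55, with camera adjusted p = 0.00165, and adjusted p = 0.371 with an estimated correlation. Cish (7.46 ± 0.14), Socs1 (5.48 ± 0.30), Osm (4.60 ± 0.33) and Pim1 (2.55 ± 0.19) rose most clearly; Cish and Socs1 are feedback inhibitors of cytokine signalling, Osm is a cytokine and Pim1 a survival kinase. Ccnd2† (-0.68 ± 0.14) fell. ERK target genes rose as a list, and 10 of 16 members rose and 1 fell, as many over the list alone, for example Egr2 (5.70 ± 0.31), Etv1 (4.87 ± 0.36) and Egr1 (3.62 ± 0.33), with Etv4 (-1.66 ± 0.16) as the one fall. ERK targets had a median of 1.83, with camera adjusted p = 0.00464, and adjusted p = 0.371 with an estimated correlation. Their median was 0.87 with normexp correction and 0.84 without the filter on dim probes. Of the cytokine and chemokine genes 16 of 24 members rose and 2 fell, with 17 up and 3 down over the list alone. Cytokine and chemokine genes had a median of 4.50, or 4.45 with dim members at bounds, with camera adjusted p = 9.54e-06, and adjusted p = 0.371 with an estimated correlation. Csf2 (at least 54.0-fold higher), Cxcl2 (5.51 ± 0.22, seen on 1 of 2 empty-vector arrays), Ccl17 (8.58 ± 0.40) and Ccl4 (4.45 ± 0.21) had the smallest p, Csf2 being the growth factor GM-CSF, and Il12a† (-2.57 ± 0.49, seen on 1 of 2 BCR-ABL arrays) and Cxcl9† (at least 5.77-fold lower) fell. ATF4 response genes, a programme of amino acid and endoplasmic reticulum stress, were higher, as 8 of 16 members rose, with 9 up over the list alone; Slc7a11 (at least 27.7-fold higher), Ddit3 (3.21 ± 0.30), Vldlr (3.66 ± 0.40) and Sesn2 (1.24 ± 0.15) led. ATF4 response genes had a median of 2.79, with camera adjusted p = 0.00136, and adjusted p = 0.626 with an estimated correlation. Their median was 1.34 without empty-vector replicate 1.

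Cell cycle genes fell almost without exception: 33 of 35 members fell, as many over the list alone. Cell cycle genes had a median of -2.61, with camera adjusted p = 2.51e-14, and adjusted p = 0.625 with an estimated correlation. Tk1 (-3.83 ± 0.21), Kif23 (-4.43 ± 0.29), Mcm7 (-2.87 ± 0.24) and Mki67 (-2.97 ± 0.28) had the smallest p; Mcm7 belongs to the replicative helicase and Mki67 marks cycling cells. Of cholesterol synthesis genes 8 of 19 members fell and 1 rose, with 1 up and 10 down over the list alone, including Fdps (-2.24 ± 0.16), Cyp51 (-1.60 ± 0.26), Fdft1 (-0.98 ± 0.17) and Hmgcs1 (-0.88 ± 0.15); Srebf2† (1.61 ± 0.36), which encodes the pathway's transcription factor, rose. Cholesterol synthesis genes had a median of -0.57, with camera adjusted p = 0.00547, and adjusted p = 0.625 with an estimated correlation. Ribosome biogenesis genes did not pass, and 2 (1 with the block) of 20 members fell, with 0 over the list alone (2 up and 3 down at an unadjusted p under 0.05): Dkc1 (-1.39 ± 0.32) and Fbl (-0.61 ± 0.17, blocked adjusted p = 0.0924). Ribosome biogenesis genes had a median of -0.26, with camera adjusted p = 0.174, and passed downward with normexp correction (0.0134) and without the filter on dim probes (0.0368). Glycolysis genes did not pass either, although 4 of 19 members rose and 1 fell, as many over the list alone, with Pgam1 (1.04 ± 0.17), Hk1 (1.11 ± 0.19), Slc2a1 (1.65 ± 0.32) and Aldoa† (1.01 ± 0.24, blocked adjusted p = 0.0608) up and Pfkm (-0.89 ± 0.16) down. Glycolysis genes had a median of 0.38, with camera adjusted p = 0.0554, and passed upward over probes seen on all arrays (0.0431), with the mean of a gene's probes (0.0449), without empty-vector replicate 2 (0.0137) and without BCR-ABL replicate 1 (0.0196). Of pro-apoptotic genes 5 of 15 members rose and 1 fell, as many over the list alone: Fas (2.68 ± 0.18), Bcl2l11 (1.97 ± 0.17), Tnfrsf10b (2.26 ± 0.24), Bax (1.07 ± 0.19) and Bik† (0.84 ± 0.23, seen on 1 of 2 empty-vector arrays) rose and Pmaip1† (-0.79 ± 0.15) fell. Pro-apoptotic genes had a median of 0.39, with camera adjusted p = 0.178. Of genes that IRF8 activates 5 of 13 members rose and 2 fell, with 5 up and 3 down over the list alone; Cdkn2b (5.79 ± 0.22), Egr1 (3.62 ± 0.33), Ctsc (1.36 ± 0.21), Klf4† (0.69 ± 0.15) and Nos2† (3.11 ± 0.90, blocked adjusted p = 0.0701) rose and Cst3 (-1.57 ± 0.22) and Il12a† (-2.57 ± 0.49, seen on 1 of 2 BCR-ABL arrays) fell. Genes that IRF8 activates had a median of 0.41, with camera adjusted p = 0.263. In the interferon response list 1 (2 with the block) of 28 members rose, with 0 over the list alone (1 up at an unadjusted p under 0.05), namely Gbp2 (3.03 ± 0.59). Interferon response genes had a median of 1.02, with camera adjusted p = 0.159. The empty-vector samples differed in this list (medians of 3.09 and 0.45 above the 75th percentile). Without replicate 1 the adjusted p was 1.58e-10 with a median of 2.45, and without replicate 2 it was 0.0304 with a median of -0.41.

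By limma, 7539 of 22762 genes (33.1%) changed between BCR-ABL and empty vectors, 3990 up and 3549 down. Rises were 52.9%, or 45.7% to 56.5% under other scalings. Each call had the same sign in both experiments, as this fit requires. At least 2-fold were 2843 of the rises and 2436 of the falls, and 572 rises and 467 falls are known only as bounds. By camera, 12 of 25 lists passed the threshold with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), against 17 by fry. The count was 3683 or 4241 without empty-vector replicate 1 or 2, and 3269 or 2855 without BCR-ABL replicate 1 or 2. Of 110 calls of named genes, 14 and 13 missed the threshold without the first and second empty-vector sample and 17 and 19 without the first and second BCR-ABL sample.

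**Figure D2:**
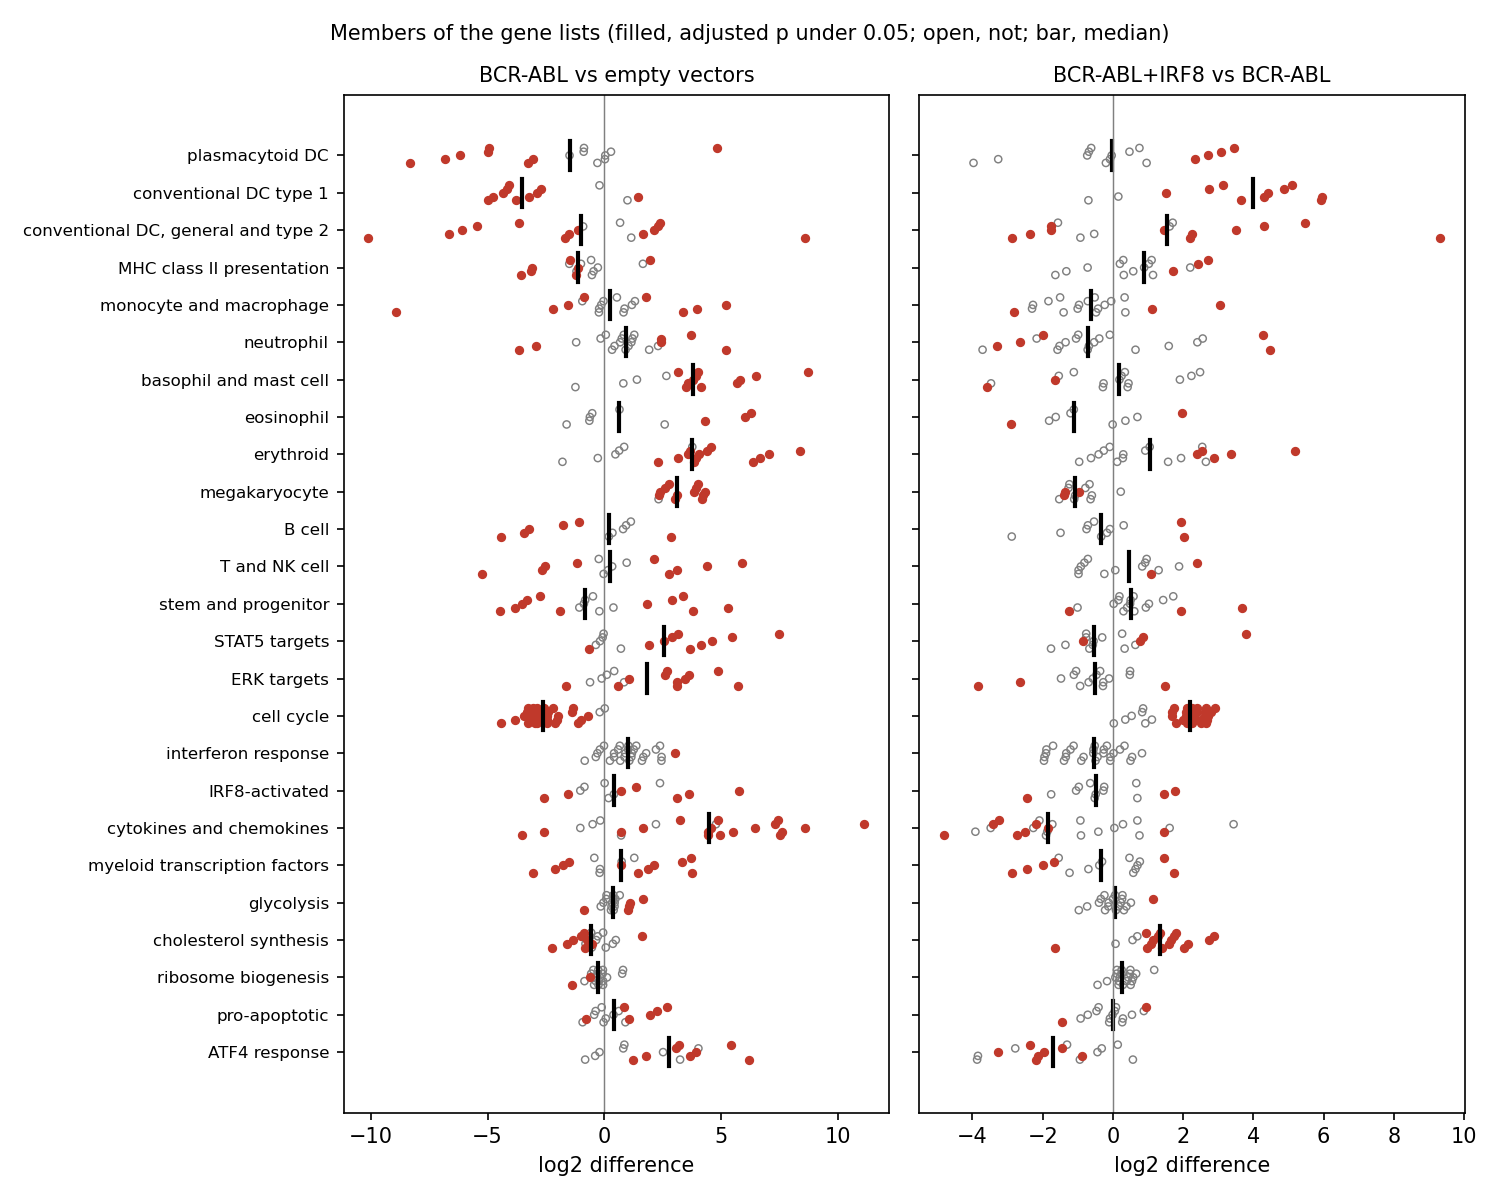
Log2 differences of the members of the 25 gene lists for BCR-ABL against empty vectors and for BCR-ABL+IRF8 against BCR-ABL; filled points have an adjusted p under 0.05, bars are list medians, and members below background in a group are drawn at their fitted value. The cell cycle median is -2.61 in the first comparison and 2.20 in the second.

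The second comparison asked what IRF8 changes when it is added to BCR-ABL cells. Flt3 was 44.2-fold higher (5.46 ± 0.29, n = 2 per group) than with BCR-ABL alone. Genes of conventional type 1 DCs rose by a median log2 of 3.98 (1.93 with normexp correction), cell cycle genes by 2.20 and cholesterol synthesis genes by 1.35. These 3 lists passed the test, but not with an estimated correlation (adjusted p = 0.649 each). Plasmacytoid DC genes did not pass as a list, except with the mean of all probes of a gene (adjusted p = 0.0487). Cytokine and chemokine genes and ATF4 response genes passed downward, with medians of -1.86 and -1.70, and gave adjusted p = 0.649 and 0.893 with an estimated correlation. The former missed without BCR-ABL+IRF8 replicate 2 (0.0641) and the latter without replicate 1 (0.0677).

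The largest rises among genes above background in both groups were Adgrg5 (7.11 ± 0.27), Tlr12 (6.72 ± 0.22), Dpp4 (6.05 ± 0.27) and Dapk2 (5.55 ± 0.47), a kinase linked to cell death. Flt3 (5.46 ± 0.29), Hic1 (5.32 ± 0.59), a transcriptional repressor, Klrb1f (5.26 ± 0.27) and Rhd (5.17 ± 0.78), a blood group antigen, came next. The largest falls were Fbp1 (-8.16 ± 1.01), Rbp4 (-7.92 ± 0.89), Cxcl2 (-4.81 ± 0.22), a chemokine for neutrophils, and Rarres1 (-4.76 ± 0.49). Chil4 (-4.55 ± 0.52), Hcar2 (-4.31 ± 0.62), the niacin receptor, Cxcl3 (-4.25 ± 0.76), another such chemokine, and Btbd11 (-4.25 ± 0.31) followed. Of genes dim in one group, Btla (at least 257-fold higher), Rtn1 (at least 142-fold higher) and Gpr82 (at least 59.1-fold higher) rose most, and Sobp (at least 14.3-fold lower), Cd200r2 (at least 13.9-fold lower) and Ces2b (at least 11.6-fold lower) fell most.

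For the type 1 subset 10 of 12 members rose, as many over the list alone. Type 1 DC genes had a median of 3.98, or 3.86 with dim members at bounds, with camera adjusted p = 1.01e-07, and adjusted p = 0.649 with an estimated correlation. Their median was 1.93 with normexp correction. Clec9a (5.10 ± 0.38), Xcr1 (at least 21.1-fold higher), Tlr3 (at least 20.1-fold higher) and Wdfy4 (2.73 ± 0.30) had the smallest p, Xcr1 being the subset's chemokine receptor. Plasmacytoid DC genes had a median of -0.04, a mean of 0.27 and a test pointing up (camera adjusted p = 0.356, or 0.0487 with a median of 0.49 for the mean of a gene's probes). Of them 4 of 15 members rose, with 4 up and 1 down over the list alone: Spib (3.43 ± 0.24), Ly6d (3.09 ± 0.51, seen on 1 of 2 BCR-ABL arrays), Lag3 (at least 3.31-fold higher) and Ccr9 (2.33 ± 0.55, seen on 1 of 2 BCR-ABL arrays, blocked adjusted p = 0.0860). Of general and type 2 conventional DC genes 7 of 16 members rose and 4 fell, with 9 up and 5 down over the list alone. General and type 2 DC genes had a median of 1.53, with camera adjusted p = 0.0314, and adjusted p = 0.893 with an estimated correlation. Their median was 0.69 with normexp correction. Btla (at least 257-fold higher), Kmo (4.31 ± 0.17), Flt3 (5.46 ± 0.29) and Fscn1 (3.51 ± 0.26) led the rises, and Irf4 (-2.86 ± 0.25), Itgax† (-2.36 ± 0.38), Sirpa† (-1.76 ± 0.35) and Clec10a† (-1.76 ± 0.41, blocked adjusted p = 0.0875) fell. That call was lost without BCR-ABL+IRF8 replicate 1 (0.385) or 2 (0.112), with quantile normalization (0.0652), the percentile of detected probes (0.0951), the series table (0.0615) and probes seen on all arrays (0.0877). MHC class II genes rose as a list, but not without BCR-ABL+IRF8 replicate 1 (0.420); 3 (1 with the block) of 15 members rose, with 5 up and 2 down over the list alone, namely Ciita (2.43 ± 0.33), Cd86 (1.70 ± 0.30, blocked adjusted p = 0.0502) and H2-Ob (2.72 ± 0.53, blocked adjusted p = 0.0661). MHC class II genes had a median of 0.89, with camera adjusted p = 0.0168, and adjusted p = 0.895 with an estimated correlation. Their median was 0.49 without BCR-ABL+IRF8 replicate 1.

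Of 35 cell cycle genes 28 rose, with 31 up over the list alone, led by Tk1 (2.89 ± 0.21), Mybl2 (2.70 ± 0.29), Kif23 (2.61 ± 0.29) and Mcm7 (2.13 ± 0.24). Cell cycle genes had a median of 2.20, with camera adjusted p = 2.62e-19, and adjusted p = 0.649 with an estimated correlation. Of 19 cholesterol synthesis genes 15 rose and Srebf2† (-1.65 ± 0.36, blocked adjusted p = 0.0650) fell, with 17 up and 1 down over the list alone. Cholesterol synthesis genes had a median of 1.35, with camera adjusted p = 8.20e-11, and adjusted p = 0.649 with an estimated correlation. Fdps (2.73 ± 0.16), Fdft1 (1.80 ± 0.17) and Pmvk (1.66 ± 0.18) were among those with the smallest p; Fdps and Fdft1 act on farnesyl diphosphate. A second Fdft1 probe, above background on 3 arrays, gave -1.16. Of the cytokine and chemokine list 7 of 24 members fell and 1 (0 with the block) rose, with 3 up and 11 down over the list alone. Cytokine and chemokine genes had a median of -1.86, with camera adjusted p = 0.0168, and adjusted p = 0.649 with an estimated correlation. Cxcl2 (-4.81 ± 0.22), Csf2 (-2.72 ± 0.21), Ccl4 (-1.85 ± 0.21) and Ccl2 (-2.50 ± 0.36) led the falls, and Il18 (1.44 ± 0.33, blocked adjusted p = 0.0574) rose. In the ATF4 response list 7 of 16 members fell, with 9 down over the list alone, among them Ddit3 (-2.37 ± 0.30), Atf5 (-3.27 ± 0.53), Sesn2 (-0.89 ± 0.15, blocked adjusted p = 0.0538) and Slc7a11 (-1.95 ± 0.34). ATF4 response genes had a median of -1.70, with camera adjusted p = 0.00237, and adjusted p = 0.893 with an estimated correlation. STAT5 targets did not pass; 3 (1 with the block) of 15 members rose and 1 fell, with 3 up and 3 down over the list alone. STAT5 targets had a median of -0.55, with camera adjusted p = 0.853. Il2ra (3.79 ± 0.25), Ccnd2 (0.78 ± 0.14, blocked adjusted p = 0.0658) and Myc (0.86 ± 0.20, blocked adjusted p = 0.0854) rose, Il2ra being an interleukin 2 receptor chain, and Cish (-0.85 ± 0.14, blocked adjusted p = 0.0548) fell. ERK targets did not pass, and 2 of 16 members fell and 1 (0 with the block) rose, with 1 up and 4 down over the list alone: Etv1 (-3.84 ± 0.36) and Egr2 (-2.64 ± 0.31) were lower and Dusp5 (1.47 ± 0.28, blocked adjusted p = 0.0509) higher. ERK targets had a median of -0.52, with camera adjusted p = 0.164.

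Erythroid genes were higher, as 5 of 19 members rose, with 7 up over the list alone: Car1 (2.40 ± 0.25), Klf1 (3.35 ± 0.49), Rhd (5.17 ± 0.78), Icam4 (2.52 ± 0.49) and Add2† (2.88 ± 0.64, blocked adjusted p = 0.0540). Erythroid genes had a median of 1.05, with camera adjusted p = 0.00237, and adjusted p = 0.893 with an estimated correlation. Their median was 0.61 over probes seen on all arrays, 1.57 with the mean of a gene's probes and 2.58 or 0.26 without BCR-ABL+IRF8 replicate 1 or 2. The BCR-ABL+IRF8 samples stood apart here, with list medians of 0.93 and 3.39 against 0.76 and 0.58 in the BCR-ABL samples, and without replicate 2 the call was lost (0.447). Megakaryocyte genes were lower, as 3 of 13 members fell, with 4 down over the list alone, including Selp (-1.37 ± 0.17) and Vwf (-1.39 ± 0.23). Megakaryocyte genes had a median of -1.08, with camera adjusted p = 0.00375, and adjusted p = 0.893 with an estimated correlation, and 0.169 without BCR-ABL+IRF8 replicate 1. Their median was -0.47 without BCR-ABL+IRF8 replicate 1. Mast cell genes had a median of 0.18, a mean of -0.24 and a test pointing down (camera adjusted p = 0.870), and 2 (1 with the block) of 15 members fell, as many over the list alone: Mitf (-1.64 ± 0.24) and Prss34 (-3.59 ± 0.78, blocked adjusted p = 0.0661). Of eosinophil genes 1 (0 with the block) of 9 members rose and 1 fell, as many over the list alone: Il5ra (at least 3.88-fold higher, blocked adjusted p = 0.0771) and Ear6 (-2.91 ± 0.35). Eosinophil genes had a median of -1.11, with camera adjusted p = 0.630. Monocyte and macrophage genes did not pass; 2 (1 with the block) of 18 members rose and 1 fell, with 2 up and 3 down over the list alone, Cx3cr1 (at least 8.17-fold higher) and Mpeg1 (1.11 ± 0.20, blocked adjusted p = 0.0616) being higher and Mrc1 (-2.81 ± 0.43) lower. Monocyte and macrophage genes had a median of -0.62, with camera adjusted p = 0.284, and passed downward without BCR-ABL+IRF8 replicate 1 (0.00561, median -1.20). Of neutrophil genes 3 (1 with the block) of 21 members fell and 2 rose, with 2 up and 5 down over the list alone; Prtn3 (4.28 ± 0.48) and Mpo (4.48 ± 0.51) rose and Mmp9 (-3.30 ± 0.45), Itgb2l (-1.99 ± 0.45, blocked adjusted p = 0.0740) and Lcn2† (-2.66 ± 0.63, blocked adjusted p = 0.0908) fell. Neutrophil genes had a median of -0.72, with camera adjusted p = 0.616. Of B cell genes 2 of 11 members rose, with 2 up and 4 down over the list alone: Cd79b (1.94 ± 0.29) and Ms4a1 (seen on 0 of 2 BCR-ABL and 1 of 2 BCR-ABL+IRF8 arrays, so no fold is given). B cell genes had a median of -0.33, with camera adjusted p = 0.738. Of T and NK cell genes 2 of 14 members rose, with 3 up and 1 down over the list alone: Tcf7 (2.39 ± 0.33) and Eomes (1.09 ± 0.17). T and NK cell genes had a median of 0.45, with camera adjusted p = 0.288, and passed upward without the filter on dim probes (0.0450, median 0.83 of 17 genes) and without BCR-ABL+IRF8 replicate 2 (0.00814, median 0.69).

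Stem and progenitor genes were higher, and 2 of 17 members rose and 1 (0 with the block) fell, as many over the list alone: Myb (3.68 ± 0.22) and Kit (1.92 ± 0.29) rose and Prom1 (-1.27 ± 0.24, blocked adjusted p = 0.0637) fell. Stem and progenitor genes had a median of 0.50, with camera adjusted p = 0.0262, and adjusted p = 0.649 with an estimated correlation. Their median was 0.24 or 0.77 without BCR-ABL+IRF8 replicate 1 or 2. The call was lost without BCR-ABL+IRF8 replicate 1 (0.335) or BCR-ABL replicate 2 (0.0583), with quantile normalization (0.0503) and with the percentile of detected probes (0.0640). Ribosome biogenesis genes passed as a list with 0 of 20 members called by limma (1 at an unadjusted p under 0.05) and 0 over the list alone, and missed without BCR-ABL+IRF8 replicate 2 (0.972) or BCR-ABL replicate 2 (0.0910). Ribosome biogenesis genes had a median of 0.27, with camera adjusted p = 0.0205, and adjusted p = 0.895 with an estimated correlation. Of myeloid transcription factors 4 of 16 members fell and 2 rose, with 4 up and 5 down over the list alone: Klf4 (-2.43 ± 0.15), Irf4 (-2.86 ± 0.25), Zeb2 (-1.99 ± 0.30) and Cebpb† (-1.68 ± 0.25) were lower and Zbtb46 (1.45 ± 0.19) and Bcl6† (1.75 ± 0.27) higher. Myeloid transcription factors had a median of -0.35, with camera adjusted p = 0.738. In the list of genes that IRF8 activates 2 (1 with the block) of 13 members rose and 1 fell, as many over the list alone: Cst3 (1.76 ± 0.22) and Il18 (1.44 ± 0.33, blocked adjusted p = 0.0574) rose and Klf4 (-2.43 ± 0.15) fell. Genes that IRF8 activates had a median of -0.49, with camera adjusted p = 0.616. Of interferon response genes 0 of 28 were called by limma, adjusted over all genes, over the list alone or unadjusted. Interferon response genes had a median of -0.54, with camera adjusted p = 0.492. Without either empty-vector sample, which is the fit of only the 2 groups compared, the list passed downward (0.0120, median -0.54) and 5 members fell, Ddx58 (-1.95 ± 0.21), Oas1a† (-1.33 ± 0.16), Oas2† (-1.39 ± 0.17), Xaf1† (-1.34 ± 0.17) and Oasl2† (-1.21 ± 0.17). Of glycolysis genes 1 of 19 members rose, as many over the list alone: Pfkm (1.15 ± 0.16). Glycolysis genes had a median of 0.06, with camera adjusted p = 0.630. Pro-apoptotic genes had a median of -0.01, a mean of -0.07 and a test pointing up (camera adjusted p = 0.853); 1 of 15 members rose and 1 fell, as many over the list alone, with Pmaip1 (0.95 ± 0.15), the BH3-only gene for Noxa, higher and Fas (-1.45 ± 0.18), a death receptor, lower.

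In all, 3450 of 22762 genes (15.2%) changed between BCR-ABL+IRF8 and BCR-ABL, 1609 up and 1841 down. With the block the count was 1992 (1052 up, 940 down). At least 2-fold were 1331 rises and 1215 falls, and 262 rises and 148 falls are bounds. By camera 11 of 25 lists passed, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and 7 by fry. Rises made up 46.6% of the calls, or 38.1% to 56.8% under other scalings, and 80.8% or 78.4% without BCR-ABL replicate 1 or 2. The count was 203 or 176 without BCR-ABL replicate 1 or 2, 1958 without either empty-vector sample, and 7165 without BCR-ABL+IRF8 replicate 1. Of 90 calls of named genes, 68 missed the threshold without either BCR-ABL sample. The BCR-ABL+IRF8 arrays also lay in another row of the slide than the other 4, so slide row and the added Irf8 vector cannot be told apart.

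Genes moved by BCR-ABL tended to move back when IRF8 was added. Of the genes called in both comparisons, 2740 changed in opposite directions, 1491 up with BCR-ABL and down with IRF8 and 1249 down and then up, against 85 in the same direction. The opposite counts were 1138 and 1432 with the percentile of detected probes, and 37 and 123 or 36 and 100 without BCR-ABL replicate 1 or 2. The largest of those that fell and came back were Btla (at least 446-fold lower, then at least 257-fold higher), Ctnnd2 (at least 599.6-fold, then at least 33.2-fold), Rtn1 (at least 249-fold, then at least 142-fold), Mycl, a member of the Myc family (at least 70.7-fold, then at least 50.3-fold), Rab39 (at least 40.3-fold, then at least 38.4-fold) and Gpr82 (at least 29.8-fold, then at least 59.1-fold). The largest of those that rose and came down were Fbp1 (11.85 ± 1.01, then -8.16 ± 1.01), Rbp4 (10.77 ± 0.89, then -7.92 ± 0.89), Chil4 (9.19 ± 0.52, then -4.55 ± 0.52), Ch25h, which makes 25-hydroxycholesterol (at least 234-fold higher, then -7.16 ± 0.43, seen on 1 of 2 BCR-ABL+IRF8 arrays), Car6, a carbonic anhydrase (at least 119-fold, then -7.84 ± 0.78, also on 1 of 2), and Crisp3 (at least 610.4-fold, then -2.80 ± 0.56). Of the 2740 genes, 2108 were not called between BCR-ABL+IRF8 and empty vectors and 632 were, 598 of them in the direction of the BCR-ABL change.

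The opposite calls were 36.3% of those in the first comparison and 79.4% of those in the second. Independent lists of these sizes would share 323 genes up and then down and 251 down and then up, and 569 in the same direction. Because both comparisons use the BCR-ABL arrays, 100 sets of unchanged groups sharing them were simulated. These sets gave at most 1 call per comparison and 0 opposite calls, which does not measure what sharing adds where genes change. Across genes the correlation of the log2 differences was -0.67 against -0.50 simulated, and the covariance -0.91 against -0.05. Part of the excess may come from the shared arrays. The count was 1607 with the block, 1464 and 1458 without empty-vector replicate 1 and 2, 160 and 136 without BCR-ABL replicate 1 and 2, and 4887 without BCR-ABL+IRF8 replicate 1.

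A form of the comparison with no shared array selected genes by their BCR-ABL difference in one experiment and read the IRF8 difference in the other. Of 6388 genes with a log2 difference of at least 1 in experiment 1, 82.5% had an IRF8 difference of the opposite sign in experiment 2, and the median IRF8 difference, signed by the first, was a log2 of -1.05. Of 6436 genes selected in experiment 2, 84.9% did so in experiment 1, with a median of -0.81. Within these, genes that rose and genes that fell in the selecting experiment both moved back, with medians of -1.13 and 0.95 in the first case and -0.80 and 0.85 in the second. These are values without a test.

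**Figure D3:**
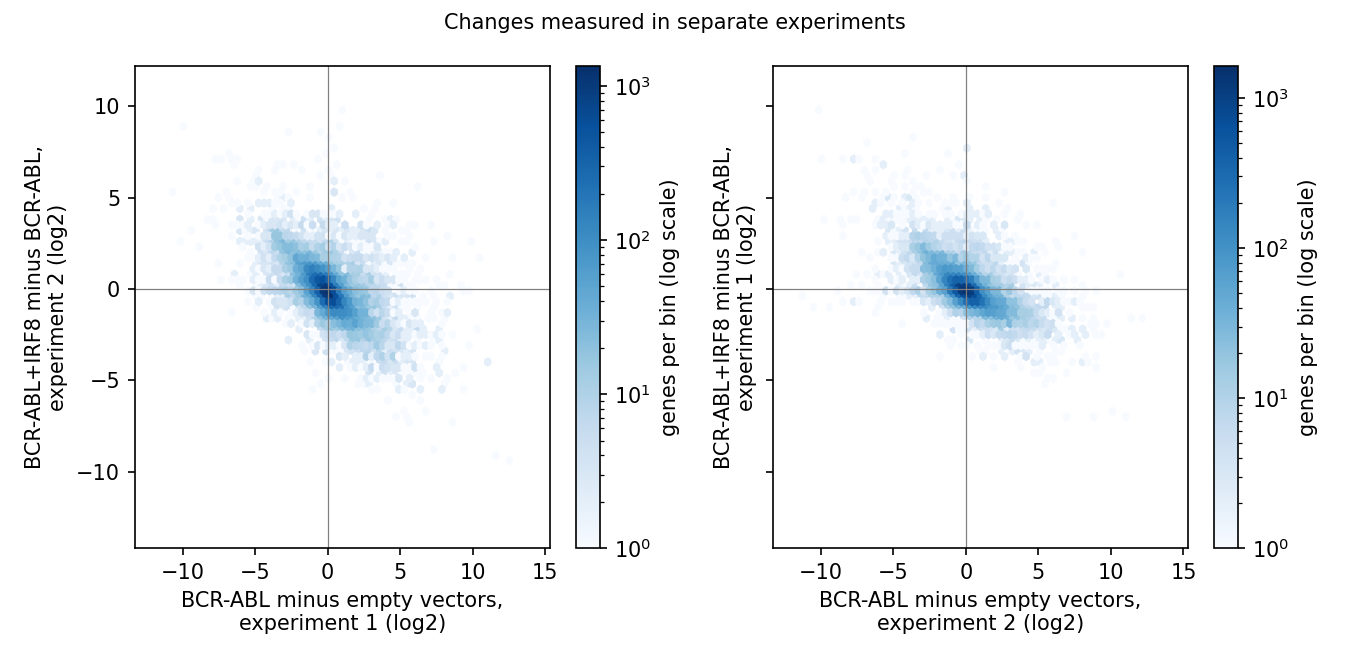
Each panel sets the log2 difference of BCR-ABL minus empty vectors in one experiment (x axis) against that of BCR-ABL+IRF8 minus BCR-ABL in the other (y axis), over all 22762 genes, with the number of genes per hexagon on a log colour scale. Most genes with large differences lie in opposite quadrants, 82.5% and 84.9% of those selected.

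The third comparison set BCR-ABL+IRF8 cells against cells with empty vectors, as a measure of what stayed different. Plasmacytoid DC genes were lower as a list, with a median log2 difference of -2.29, and erythroid, mast cell and megakaryocyte genes higher, with medians of 5.33, 3.87 and 2.52 (adjusted p = 0.368 each with an estimated correlation). With normexp correction the plasmacytoid DC and erythroid medians were -1.16 and 3.14. STAT5 targets and cytokine and chemokine genes were higher too (0.185 each with that correlation). Conventional DC type 1 genes passed upward with a median of 0.77, but 0 of 12 were called, the list medians were 1.56 in experiment 1 and 0.03 in experiment 2, and the adjusted p was 0.648 with an estimated correlation. That pass was lost without empty-vector replicate 1 (0.402) or BCR-ABL+IRF8 replicate 2 (0.104). Cish was 98.0-fold higher (6.61 ± 0.14, n = 2 per group).

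The largest rises among genes above background in both groups were Ccl24 (9.27 ± 0.57), Hbb-b2 (8.75 ± 0.90), a globin, Ccl17 (7.66 ± 0.40) and Csta2 (7.28 ± 0.71), a protease inhibitor. Gstt1 (7.08 ± 0.31), Hbb-bt (6.95 ± 0.51), Cish (6.61 ± 0.14) and Arg1 (6.50 ± 1.34, blocked adjusted p = 0.0718) came next. The largest falls were Cx3cr1 (-5.88 ± 0.26), Upb1 (-5.86 ± 0.54), Cox6a2 (-5.46 ± 1.10, blocked adjusted p = 0.0551), a cytochrome c oxidase subunit, and Skint3 (-5.43 ± 0.17). Ly6d (-5.25 ± 0.51), Atp1b1 (-5.11 ± 0.53), a subunit of the sodium pump, Prss34 (-4.83 ± 0.78), a mast cell protease, and Cd300e (-4.79 ± 0.23) followed. Of genes dim in one group, Tph1 (at least 834-fold higher), Hbb-bs (at least 399.9-fold higher) and Atp1b2 (at least 145-fold higher) rose most, and Col1a1 (at least 52.5-fold lower, blocked adjusted p = 0.0553), a collagen chain, Setbp1 (at least 18.6-fold lower) and Adgre4 (at least 16.5-fold lower) fell most. Col1a1 had log2 signals of -1.05 and 3.08 in the empty-vector samples, and its log2 difference of -6.62 was -4.55 without replicate 2. Its call was lost without any one BCR-ABL or BCR-ABL+IRF8 sample (adjusted p = 0.0679 to 0.0904).

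Of plasmacytoid DC genes 7 of 15 members fell, with 8 down over the list alone, including Runx2 (-3.99 ± 0.33), Spib (-2.77 ± 0.24), Tcf4 (-2.58 ± 0.23) and Upb1 (-5.86 ± 0.54). Plasmacytoid DC genes had a median of -2.29, with camera adjusted p = 5.38e-05, and adjusted p = 0.368 with an estimated correlation. Their median was -1.16 with normexp correction, -0.92 over probes seen on all arrays and -1.51 without BCR-ABL+IRF8 replicate 2. In the conventional DC type 1 list, which passed upward, 0 of 12 members were called by limma (3 at an unadjusted p under 0.05, all up) and 0 over the list alone. Type 1 DC genes had a median of 0.77, with camera adjusted p = 0.0244, and adjusted p = 0.648 with an estimated correlation. Their median was 0.12 or 1.31 without empty-vector replicate 1 or 2 and 0.44 without BCR-ABL+IRF8 replicate 1. General and type 2 conventional DC genes had a median of -0.34, a mean of 0.11 and a test pointing down (camera adjusted p = 0.810); 3 of 16 members rose and 3 fell, with 4 up and 5 down over the list alone: Ccl17 (7.66 ± 0.40), Fscn1 (2.40 ± 0.26) and Ccl22† (3.26 ± 0.41) up and Clec4a4 (-4.20 ± 0.37), Cd209a (-4.38 ± 0.42) and Kmo† (-1.14 ± 0.17) down. Of MHC class II genes 1 of 15 members fell, as many over the list alone: Cd80 (-1.18 ± 0.18), a co-stimulatory ligand. MHC class II genes had a median of -0.28, with camera adjusted p = 0.319, and passed downward without empty-vector replicate 1 (0.0431, median -0.46) and without BCR-ABL+IRF8 replicate 1 (0.00927, median -0.75).

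Of erythroid genes 15 of 19 members rose, with 16 up over the list alone, led by Cited4 (5.31 ± 0.35), Hbb-bt (6.95 ± 0.51), Car1 (3.03 ± 0.25) and Add2 (at least 44.3-fold higher). Erythroid genes had a median of 5.33, or 3.93 with dim members at bounds, with camera adjusted p = 9.99e-12, and adjusted p = 0.368 with an estimated correlation. Their median was 3.14 with normexp correction and 3.55 over probes seen on all arrays. A second Car1 probe gave 6.14. The BCR-ABL+IRF8 samples had list medians of 0.93 and 3.39 and the empty-vector samples -2.52 and -2.65. Of mast cell genes 9 of 15 members rose and 1 fell, with 12 up and 1 down over the list alone; Il13 (at least 113-fold higher), Mcpt4 (at least 18.8-fold higher), Cma1 (6.04 ± 0.77, seen on 1 of 2 empty-vector arrays) and Cpa3 (5.81 ± 0.81) had the smallest p, and Prss34 (-4.83 ± 0.78) fell. Basophil and mast cell genes had a median of 3.87, with camera adjusted p = 2.02e-07, and adjusted p = 0.368 with an estimated correlation. Their median was 2.51 without empty-vector replicate 1. Of megakaryocyte genes 11 of 13 members rose, with 12 up over the list alone, such as Vwf (2.52 ± 0.23), Itga2b (3.19 ± 0.32), Tubb1 (2.14 ± 0.22) and Pf4 (3.03 ± 0.32). Megakaryocyte genes had a median of 2.52, with camera adjusted p = 1.16e-09, and adjusted p = 0.368 with an estimated correlation. Of eosinophil genes 2 of 9 members rose, with 3 up and 1 down over the list alone: Ear2 (5.07 ± 0.40) and Ear1 (4.92 ± 0.43). Eosinophil genes had a median of 0.95, with camera adjusted p = 0.0565, 0.0486 with the block, and passed upward with normexp correction (0.0405, median 0.49), over probes seen on all arrays (0.00786), without empty-vector replicate 2 (0.0318) and without BCR-ABL+IRF8 replicate 2 (0.0135). Of monocyte and macrophage genes 3 of 18 members fell and 1 rose, as many over the list alone, with Cx3cr1 (-5.88 ± 0.26), Ms4a6c (-2.42 ± 0.28) and Ccr2 (-1.37 ± 0.21) lower and Mrc1 (2.41 ± 0.43) higher. Monocyte and macrophage genes had a median of -0.16, with camera adjusted p = 0.469, and passed downward without BCR-ABL+IRF8 replicate 1 (0.0232, median -0.81). For neutrophil genes 2 (1 with the block) of 21 members rose and 1 fell, with 4 up and 2 down over the list alone: Chil3 (4.48 ± 0.58) and Gfi1 (3.32 ± 0.67, blocked adjusted p = 0.0635) rose and Mmp9 (-2.63 ± 0.45) fell. Neutrophil genes had a median of 0.21, with camera adjusted p = 0.217, and passed upward without empty-vector replicate 2 (0.0284, median 0.68) and without BCR-ABL+IRF8 replicate 2 (0.00374, median 1.09). B cell genes were lower, but not over probes seen on all arrays (0.0624); 4 of 11 members fell, with 5 down over the list alone: Cd79b (-2.47 ± 0.29), Bank1 (-1.79 ± 0.22), Blk (at least 3.1-fold lower) and Cd22 (-2.09 ± 0.28). B cell genes had a median of -1.15, with camera adjusted p = 0.0132, and adjusted p = 0.321 with an estimated correlation. Their median was -0.39 with normexp correction, -0.53 without the filter on dim probes and -0.58 without BCR-ABL+IRF8 replicate 2. For T and NK cell genes 5 of 14 members rose and 2 fell, with 7 up and 4 down over the list alone; Eomes (at least 10.1-fold higher), Gata3 (at least 3.93-fold higher), Thy1† (4.42 ± 0.75), Il2rb† (3.08 ± 0.53, seen on 1 of 2 empty-vector arrays, blocked adjusted p = 0.0559) and Gzma† (4.93 ± 1.02) rose and Cd2 (-3.48 ± 0.27) and Cd5 (-3.38 ± 0.50) fell. T and NK cell genes had a median of 0.51, with camera adjusted p = 0.0733, and passed upward without the filter on dim probes (0.0283, median 0.89 of 17 genes) and without BCR-ABL+IRF8 replicate 2 (0.00964, median 1.43).

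In the STAT5 list 8 of 15 members rose, with 10 up and 1 down over the list alone, including Cish (6.61 ± 0.14), Il2ra (5.71 ± 0.25), Socs1 (4.72 ± 0.30) and Pim1 (1.97 ± 0.19). STAT5 targets had a median of 1.97, with camera adjusted p = 1.97e-07, and adjusted p = 0.185 with an estimated correlation. In the ERK list 7 of 16 members rose and 1 fell, with 10 up and 2 down over the list alone, including Egr2 (3.06 ± 0.31), Egr1 (2.57 ± 0.33) and Phlda1 (2.99 ± 0.50), and Etv4 (-1.18 ± 0.16) fell. ERK targets had a median of 1.31, with camera adjusted p = 0.00229, and adjusted p = 0.309 with an estimated correlation. Their median was 0.63 with normexp correction. In the cytokine and chemokine list 12 of 24 members rose, with 15 up and 1 down over the list alone, led by Csf2 (at least 8.17-fold higher), Ccl17 (7.66 ± 0.40), Ccl24 (9.27 ± 0.57) and Ccl2 (4.94 ± 0.36). Cytokine and chemokine genes had a median of 1.90, with camera adjusted p = 1.90e-08, and adjusted p = 0.185 with an estimated correlation. Cholesterol synthesis genes were higher, as 8 (3 with the block) of 19 members rose, with 12 up over the list alone, including Idi1 (1.76 ± 0.29), Mvd (1.05 ± 0.20) and Mvk (0.76 ± 0.14, blocked adjusted p = 0.0686). Cholesterol synthesis genes had a median of 0.64, with camera adjusted p = 2.78e-07, and adjusted p = 0.321 with an estimated correlation. Glycolysis genes were higher as a list, with one call, Hk1 (1.34 ± 0.19), which was also the one over the list alone. Glycolysis genes had a median of 0.38, with camera adjusted p = 0.000791, and adjusted p = 0.648 with an estimated correlation. Their median was 0.70 without empty-vector replicate 2 and 0.61 without BCR-ABL+IRF8 replicate 2. Pro-apoptotic genes were higher, as 4 of 15 members rose, as many over the list alone: Bcl2l11 (2.23 ± 0.17), Fas (1.23 ± 0.18), Tnfrsf10b (1.55 ± 0.24) and Bik (1.38 ± 0.23, seen on 1 of 2 empty-vector arrays), Bcl2l11 encoding the death activator Bim. Pro-apoptotic genes had a median of 0.15, with camera adjusted p = 0.0153, and adjusted p = 0.368 with an estimated correlation. The pro-apoptotic call was lost without empty-vector replicate 1 (0.0566) or BCR-ABL+IRF8 replicate 2 (0.0854). ATF4 response genes passed with one call, Slc7a11 (at least 7.16-fold higher), also over the list alone. ATF4 response genes had a median of 0.41, with camera adjusted p = 0.0382, and adjusted p = 0.705 with an estimated correlation. Their median was -0.13 or 0.88 without empty-vector replicate 1 or 2 and 0.77 without BCR-ABL+IRF8 replicate 2. The ATF4 list missed without BCR-ABL+IRF8 replicate 2 (0.174) and over probes seen on all arrays (0.0613), and turned down without empty-vector replicate 1 (0.884). Cell cycle genes were lower, as 2 (1 with the block) of 35 members fell, with 1 down over the list alone: Kif23 (-1.82 ± 0.29) and Tk1 (-0.94 ± 0.21, blocked adjusted p = 0.0953); the list missed without empty-vector replicate 1 (0.120) or BCR-ABL+IRF8 replicate 1 (0.579). Cell cycle genes had a median of -0.51, with camera adjusted p = 0.00255, and adjusted p = 0.749 with an estimated correlation. Their median was -0.33 without empty-vector replicate 1 and -0.17 or -0.86 without BCR-ABL+IRF8 replicate 1 or 2.

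Stem and progenitor genes did not pass, and 5 (2 with the block) of 17 members fell and 4 rose, with 6 up and 5 down over the list alone: Sox4 (-2.29 ± 0.35), Egfl7† (-1.61 ± 0.27), Kit† (-1.41 ± 0.29, blocked adjusted p = 0.0588), Hoxa7† (-3.53 ± 0.73, blocked adjusted p = 0.0567) and Hoxa5† (at least 4.21-fold lower, blocked adjusted p = 0.0694) fell and Procr (3.31 ± 0.33), Prom1 (2.09 ± 0.24), Mycn (4.27 ± 0.55, seen on 1 of 2 empty-vector arrays) and Meis1† (2.31 ± 0.41, blocked adjusted p = 0.0536) rose. Stem and progenitor genes had a median of 0.20, with camera adjusted p = 0.400. Myeloid transcription factors had a median of -0.10, a mean of 0.18 and a test pointing down (camera adjusted p = 0.919); 3 of 16 members fell and 2 (1 with the block) rose, with 4 up and 3 down over the list alone, Klf4 (-1.74 ± 0.15), Tcf4 (-2.58 ± 0.23) and Ikzf1 (-1.09 ± 0.17) being lower and Cebpb (2.06 ± 0.25) and Gfi1 (3.32 ± 0.67, blocked adjusted p = 0.0635) higher. In the list of genes that IRF8 activates 3 of 13 members rose and 1 fell, with 3 up and 2 down over the list alone: Cdkn2b (5.14 ± 0.22), Egr1 (2.57 ± 0.33) and Ctsc (1.09 ± 0.21, blocked adjusted p = 0.0639) rose and Klf4 (-1.74 ± 0.15) fell. Genes that IRF8 activates had a median of 0.19, with camera adjusted p = 0.319. In the interferon response list 1 (0 with the block) of 28 members rose, with 0 over the list alone (1 up at an unadjusted p under 0.05), namely Gbp2 (2.86 ± 0.59, blocked adjusted p = 0.0541). Interferon response genes had a median of 0.18, with camera adjusted p = 0.357. The list's test gave 1.00e-12 without empty-vector replicate 1 (median 1.64) and 2.00e-06 without replicate 2 (median -1.05). Of ribosome biogenesis genes 0 of 20 were called by limma, adjusted over all genes, over the list alone or unadjusted, and the list passed upward without BCR-ABL+IRF8 replicate 1 (0.000192, median 0.47) and downward without replicate 2 (0.0267, median -0.23). Ribosome biogenesis genes had a median of 0.12, with camera adjusted p = 0.499.

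The test called 2906 of 22762 genes (12.8%) between BCR-ABL+IRF8 and empty vectors, 1560 up and 1346 down, and 1835 with the block (1101 up, 734 down). At least 2-fold were 1338 rises and 844 falls, and 385 rises and 161 falls are bounds. Of 25 lists 14 passed by camera, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and 11 by fry. The count was 828 or 1095 without empty-vector replicate 1 or 2, 1121 without either BCR-ABL sample, and 4448 without BCR-ABL+IRF8 replicate 1. Of 88 calls of named genes, 28 and 25 missed the threshold without the first and second empty-vector sample and 25 without either BCR-ABL sample.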

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

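No called named gene changed direction under any alternative run. With IRF8 added a second Fdft1 probe gave -1.16 against 1.80. The Irf8 differences and the return across experiments kept direction too, while the balance of rises and falls among calls did not. The causes of the changes below were not tested. Without the filter on dim probes 2017 genes changed between BCR-ABL+IRF8 and BCR-ABL and 1796 between BCR-ABL+IRF8 and empty vectors. Opposite calls were 1650, and the return was -0.71. Irf8 against empty vectors (-1.51) missed there (adjusted p = 0.0767). With the experiment as a replicate block these counts were 1992, 1835 and 1607 (Irf8 adjusted p = 0.0693). With only the 2 groups compared they were 1958, 1121 and 1627 (Irf8 0.0900), while BCR-ABL against empty vectors rose to 10254. In the main fit groups of unequal spread share a variance. Among the lists the block changed 1 call, that of eosinophil genes against empty vectors. Selecting genes at a log2 difference of at least 2 gave a return of -1.46 against -0.93 (both as the mean of the experiments used either way round). Rises were 52.9%, 46.6% and 53.7% of the calls in the 3 comparisons, and under the 4 other scalings 45.7% to 56.5%, 38.1% to 56.8% and 48.0% to 54.5%, so which direction held more genes depended on the scaling. No scaling moved the median of all genes by more than a log2 of 0.1.

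Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons (3, 1 and 3 at an unadjusted p under 0.05), against 12, 11 and 14 with the preset one, and fry called 17, 7 and 11. Of the calls of named genes in the 3 comparisons, in order, the block ended 2 of 110, 15 of 90 and 9 of 88. For BCR-ABL+IRF8 against BCR-ABL and against empty vectors, testing without a filter ended 19 and 16 and fitting only the groups compared 14 and 25.

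Leaving out each sample in turn, where the lone sample of a group is assumed to vary like the other groups, gave 2855 to 10254 genes for BCR-ABL against empty vectors, 176 to 7165 for BCR-ABL+IRF8 against BCR-ABL, 828 to 4448 for BCR-ABL+IRF8 against empty vectors, and 136 to 4887 opposite calls. The Irf8 differences spanned -4.10 to -3.92, 2.08 to 2.92 and -1.93 to -1.09. Between 12 and 15, 7 and 12, and 12 and 17 lists passed. Lists that turned with a sample left out had wide ranges of adjusted p over these sets. Interferon response genes spanned 1.58e-10 to 0.265 for BCR-ABL against empty vectors and 1.00e-12 to 0.536 for BCR-ABL+IRF8 against empty vectors, and without empty-vector replicate 2 they passed downward (0.0304 and 2.00e-06). In the latter comparison ribosome biogenesis spanned 0.000192 to 0.756 and the ATF4 response 1.84e-06 to 0.884, the former turned without BCR-ABL+IRF8 replicate 2 (0.0267) and the latter without empty-vector replicate 1.

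With the experiment numbers of the BCR-ABL+IRF8 samples crossed in the block, an alternative chosen after seeing the data, 7137, 2927 and 2245 genes changed and 2373 were opposite calls. On each array only 51.4% to 54.3% of the probes lay well above background, so changes among dim genes are known only as bounds.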

Other observations

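Unlike the list medians and scalings they draw on, the tests in this part were chosen after the values were seen. So were the genes named, except Cdkn2b, Col1a1 and Hbb-bs. Inhibitors of the cell cycle were among the genes that moved with BCR-ABL. Cdkn2a, which encodes p16 and p19Arf, was higher than with empty vectors in BCR-ABL cells by a log2 of 8.94 (adjusted p = 0.000743) and in BCR-ABL+IRF8 cells by 8.80, and was above background on 1 of 2 empty-vector arrays. Cdkn1a, the gene for p21, rose 9.65-fold (3.27) with BCR-ABL, and Cdkn2c, the gene for p18, fell (-3.01). Cdkn2b, the gene for p15, was higher by 5.79 with BCR-ABL and differed by -0.65 (adjusted p = 0.115) when IRF8 was added. When IRF8 was added Cdkn1a fell (-0.78, adjusted p = 0.0282) and Cdkn2c rose (1.58, 0.0486). These 2 calls were lost with the block (0.0652 and 0.0809) and without any one empty-vector or BCR-ABL sample (0.0638 to 0.215). Of 14 measured genes of the kallikrein 1 family, secreted serine proteases with near-identical copies, 10 rose with BCR-ABL (family median 4.76). Without any one of the empty-vector or BCR-ABL samples 0 of them were called, and without either BCR-ABL+IRF8 sample 14. By limma 0 were called when IRF8 was added (median -3.29, 8 at an unadjusted p under 0.05). Against empty vectors 0 were called in BCR-ABL+IRF8 cells (median 1.68, 0 unadjusted), but 12 without BCR-ABL+IRF8 replicate 2.

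The samples of a group also differed from each other, in values without a test. The genes below were picked for such differences and stand for no wider group. In log2 signal above the array's 75th percentile, BCR-ABL+IRF8 replicates 1 and 2 had 3.23 and -6.68 for Gzmg, 4.37 and -5.01 for Gzme, 1.13 and -6.66 for Gzmd, and 0.13 and -5.10 for Ifng, interferon gamma. They had -0.95 and 4.45 for Alas2, -1.48 and 4.54 for Slc4a1, 4.62 and 9.10 for Hba-a1, and 2.35 and 5.91 for Hbb-bs. Empty-vector replicates 1 and 2 had -1.05 and 3.08 for Col1a1, 0.19 and 4.14 for Col1a2, 1.70 and 5.21 for Sparc, and -2.87 and 0.02 for Postn.

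Cell cycle genes were lower with BCR-ABL (median -2.61) and higher again with IRF8 (2.20). Array scaling is argued against, as the median was still -2.46 under the scaling that made it smallest. Less growth of the cells as a whole would lower ribosome biogenesis genes too. Their medians, -0.26 (member SD 0.48) and 0.27 with IRF8, went the same way but less, so do not decide. Cdkn2a alone is argued against as the switch, as it differed by -0.13 (SE 0.52) with IRF8 added. Cdkn2c moved the wrong way for an inhibitor, and Cdkn1a and Cdkn2b were not excluded. Less growth or fewer dividing cells stay open as hypotheses. Bulk RNA does not separate them from a change in each cell.

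Interferon response genes differed between empty-vector replicates 1 and 2 by a median log2 of 2.79. Replicate 2 stood apart, with a list median of 0.45 against 3.09 in replicate 1 and 1.91 to 3.15 in the other 4 arrays. The choice of scaling is argued against, as the lowest difference under another of the scalings run was 2.46. A difference shared by all samples of an experiment is argued against as well, as the other pairs differed by -0.22 and 0.25. More plasmacytoid DCs in replicate 1 than in replicate 2 as the direct source of this RNA would move their own genes by as much, and these differed by 0.33, with an SD of 0.48 among 15 members. Unequal exposure of the 2 cultures to interferon, released by such cells or from elsewhere, may account for the difference and was not tested.

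Erythroid, megakaryocyte and mast cell genes were higher with BCR-ABL, and 12 of 19, 13 of 13 and 10 of 15 of them were above background in both empty-vector samples. The choice of scaling is argued against as the whole cause, since the lowest median of a list under another was 1.33, for erythroid genes with normexp correction (3.76 before). A lower share of DCs alone would raise alike those genes that only other lineages express. These 47 genes had a median of 3.76 and 73 genes of monocytes, neutrophils, eosinophils, B cells and T and NK cells 0.65, a gap of 3.12 that exceeded the SD of either set (2.16 and 2.65). More erythroid, megakaryocyte and mast cells, or their genes expressed in other cells, may account for the pattern, and bulk RNA leaves both open. The sort selected the vectors' markers and not a lineage.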
